A study of Mus musculus with 17 samples.

How the data were processed

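The data were 17 ChIP-seq libraries from bone marrow-derived macrophages of C57BL/6 mice on the 7th day of differentiation: 16 ChIP libraries for 5 factors and 1 input library. Per the labels each combination of factor, treatment and time was 1 library, so samples were grouped by these 3 labels and no replicates were pooled. Reads were aligned with Bowtie2 2.2.6 and peaks called with MACS2 2.1.0.20150731 on mm10/GRCm38 according to the submitters' processing notes. The settings of both tools are not given in the sources used here. Peaks had been called per sample, from a single library each.

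Each deposited list held peaks in the 10-column narrowPeak layout without a header. The deposited fold enrichment is a ratio of the signal at the summit to the control, computed per peak by the authors' peak caller. The deposited −log10 p and −log10 q values were computed per peak against the control in the same step. The deposited score was 10 times the −log10 q in all lists except untreated JUNB, where it was 10 times the −log10 p. The last deposited column, the summit offset in bp from the start of the peak, gave the summit positions. These values from the authors are not comparable between libraries of different depth and were used to rank or filter peaks within a list, and as described below to recover the depth of each library and to thin a list to the depth of another.

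Peaks on chromosomes 1 to 19, X and Y were used, and ChIP peaks overlapping a peak of the input list were removed, which took between 0 and 39 peaks from a list. The lists then held 24927 and 21481 peaks for STAT6 (IL4, IFNg+IL4), 244, 4189 and 8226 for IRF1 (untreated, IFNg, IFNg+IL4), 9229, 7428 and 5556 for JUNB, 5540, 21499 and 6278 for CEBPB, and 495, 13211, 9645, 3034 and 3402 for MYC (untreated, IL4 2 h, IL4 4 h, IFNg+IL4 2 h, IFNg+IL4 4 h). The untreated JUNB list had been thresholded on p, as its values show, and held 5355 peaks with a −log10 q of at least 2, the threshold that the other lists met.

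Read counts per library were not used here, and depth was recovered from the peak columns. The −log10 p and fold of a peak fix its pileup and its expected background, and the smallest steps of these values give the depth of the library relative to the input. This assumes that the same input served every list and that its scaling was linear. Up to 2000 peaks per list with a −log10 p of at most 80 were used. Relative depths were 1.13 and 1.08 for STAT6, 1.54, 0.446 and 0.929 for IRF1, 1.55, 1.01 and 1.23 for JUNB, 1.46, 1.33 and 1.31 for CEBPB, and 0.555, 0.573, 0.876, 0.329 and 0.368 for MYC, in the order given above. For the 7 libraries shallower than the input (2 of IRF1 and all 5 of MYC) fit scores were 0.398 to 0.475, so part of their values lay off the steps. The others scored at least 0.959, but from values selected beforehand and with another tolerance. The scores of the 2 kinds of library are therefore not on 1 scale.

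A peak of one list was kept when at least 1 bp overlapped a peak of the other. The share kept was computed in both directions for 11 pairs of lists, with exact Clopper-Pearson 95% intervals, beside the mean share after 100 random circular shifts of the second list per chromosome (20 shifts for overlaps between factors). The interval on the share kept of 9229 untreated JUNB peaks ran from 45.9 to 48.0%, and on that of 244 untreated IRF1 peaks from 91.1 to 97.1%. Shares were also computed in 10 classes of equal size by −log10 p. Peaks listed with IFNg were split by the presence of an untreated peak. Lost and kept peaks were compared for overlap with peaks of another factor. Both were set beside 10000 random sets of peaks matched on the 10 classes, drawn from all peaks of the list, the compared ones included.

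Gene positions came from a RefSeq table of GRCm38 with 21887 protein-coding genes on these chromosomes. A gene was near a peak when the summit lay within 20 kb of its span. For each of 7 gene lists the share of genes near a peak was placed among 10000 random lists of as many genes, matched on 5 classes of gene length. The share of peaks near the list's genes that were kept was placed among 10000 random sets of as many peaks of the same library, matched on the 10 classes of −log10 p. The lists were IL4 response (30 genes), IFNg response (35 of 36, since Cxcl11 is a pseudogene in the reference), ribosome biogenesis and growth genes known as MYC targets (30), inflammatory and AP-1 genes (30), macrophage identity (25), markers of other cell types that the culture could hold (25) and genes of other organs (25). Socs1 was in both the IL4 and the IFNg list.

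The comparisons, the gene lists, the window, the overlap rule, the naming rule and the alternatives were chosen before the data were examined, except those listed as added. Genes were named by a fixed rule: per pair, up to 30 genes of the lists that go with the treatment (IL4 response for STAT6, IL4 response and growth genes for MYC, IFNg response for IRF1, IFNg response and inflammatory and AP-1 genes for JUNB and CEBPB), ordered by their strongest −log10 p in either list. Peaks were named as the 5 strongest of each list with no peak of the other within 500 bp and the 5 strongest present in both, after the nearest protein-coding gene within 100 kb. Genes named outside the rule are marked as such in the text.

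The reference held no genome sequence, strand or exons, which led to 3 deviations from the plan. Motifs under summits were not run. Windows were set around the gene span instead of the transcription start. Position was classed as within 1 kb of either gene end, inside a gene or intergenic. The number of shifts for overlaps between factors was lowered from 100 to 20 to limit run time.

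The alternatives chosen beforehand were a −log10 q of at least 5 in both lists or in the first list only, a fold of at least 5, a reciprocal overlap of 50%, the summit inside the other peak, peaks within 500 bp, input peaks kept, the same number of strongest peaks, windows of 5 kb and 50 kb, and a gene-end window of 2.5 kb. Chosen after the data were seen were a −log10 q of at least 2 for JUNB, thinning of the deeper list to the depth of the other, the alternatives for peaks gained with IFNg and for overlaps between factors, and the leaving out of 3 macrophage genes. Thinning drew the pileup of each peak binomially at the lower depth in 100 draws and kept peaks that still passed the threshold, without calling peaks anew.

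The tests of depth and enrichment in the closing section were also designed after the values were seen. They compare a set of peaks with random peaks matched on −log10 p and fold, and a gene list with random genes that have as many peaks. An explanation by enrichment was counted as excluded for a gene list only where the difference was above 5 percentage points and lay in the outer 2.5% divided by 8 sets in both draws, and stayed there when each gene with a peak was left out in turn. An explanation by depth was counted as fitting where the ratio of peak numbers after thinning came within 1.1, and as excluded where every draw stayed beyond 1.1 after an allowance of 6.27% for the error of thinning in the self-test. The share of depth that would bring the ratio within 1.1 was found by thinning further in steps of 0.01. These bounds were set and changed with the values in view. A first version used the draw of genes alone, which would have excluded enrichment for IRF1, and a second counted depth as excluded only beyond 1.5, which left depth open for IRF1. The leaving out of single genes was added last, and without it enrichment would have been excluded for MYC at 4 h near macrophage identity genes.

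The steps were tested on simulated data. Lists made with a known overlap gave it back within 0.213 percentage points in the 11 pairs. Of 50 random peak sets 6% fell under the 5th percentile, and of 50 sets with kept peaks cut by 0.5 100% did, and for gene sets it was 0% and 100%. Relative depth came back within 0.00909% at 6 depths. The simulated values lay exactly on the steps, while part of the values in the libraries shallower than the input did not. The error for those libraries may therefore be larger. The test of thinning took depths as known, so its difference covers no error in depth. Thinned lists differed from lists drawn at the lower depth by up to 6.27% (median −2.30%) in 30 simulated pairs of 60000 sites, with fewer peaks in 28 of them. A first limit of 5% on that difference was not met and was dropped, since sites below the threshold at full depth are missed by construction. Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3 and Matplotlib 3.10.9 were used.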

Results

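Binding of 5 transcription factors was mapped by ChIP-seq in macrophages grown from the bone marrow of C57BL/6 mice and used on day 7 of differentiation. The cells were untreated or received interleukin 4 (IL4, 10 ng/ml), which drives the alternative form of macrophage activation, interferon gamma (IFNg, 100 ng/ml), which drives the classical form, or both cytokines together. STAT6, the factor activated by the IL4 receptor, was mapped after 2 h of IL4 with or without IFNg. IRF1, an interferon-induced factor, JUNB, a subunit of AP-1, and CEBPB, a leucine zipper factor of myeloid cells, were mapped in untreated cells and after 4 h of IFNg or IFNg+IL4. MYC, a regulator of growth and ribosome production, was mapped in untreated cells and after 2 h and 4 h of IL4 or IFNg+IL4. Each group was 1 library with no replicates, so no p-values were computed and each comparison describes these libraries.

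The 16 ChIP lists held between 244 peaks (IRF1, untreated) and 24927 peaks (STAT6, IL4), and the libraries ranged from 0.329 to 1.55 times the depth of the input library. A peak was counted as kept when a peak of the other list overlapped it by at least 1 bp, and as near a gene when its summit lay within 20 kb of the gene's span. Shares of peaks carry exact Clopper-Pearson 95% intervals in parentheses, which cover counting error only. Percentiles place a gene list among 10000 random lists of genes of like length, or the peaks near it among 10000 random sets of peaks of like strength from the same library. Such sets of peaks treat neighbouring peaks at a gene as independent, so their percentiles can be too extreme. Percentiles among random genes with as many peaks are named as such. The −log10 p values are the authors' own values per peak and rank peaks within 1 list only, so a difference between lists in such a value shows no change. Positions are those of the mouse genome build mm10/GRCm38.

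**Figure D1:**
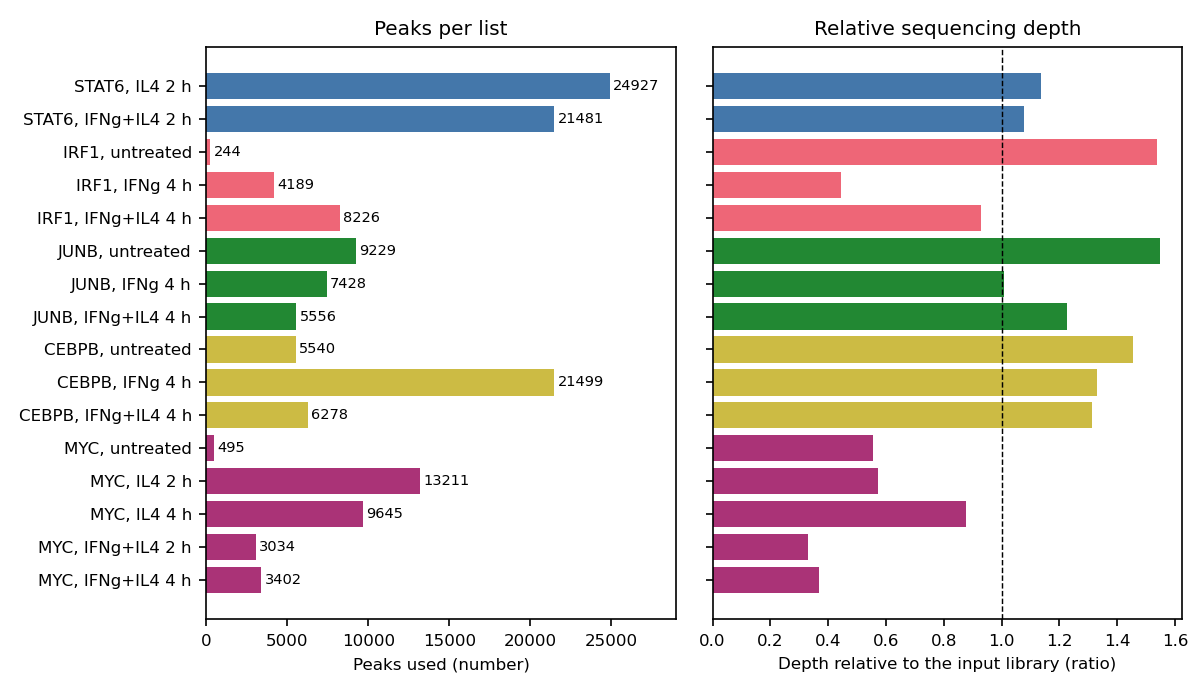
Number of peaks used per ChIP library (left, horizontal bars) and depth of the library relative to the input library (right, ratio, dashed line at 1), for the 16 ChIP libraries grouped by factor and treatment, 1 library per group and therefore no error bars. CEBPB had 5540 peaks untreated, 21499 with IFNg and 6278 with IFNg+IL4 at depths between 1.31 and 1.46, whereas the 5 MYC libraries spanned depths from 0.329 to 0.876.

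With IL4 alone STAT6 peaks lay near 28 of the 30 genes of the IL4 response list, and with IFNg+IL4 near 27 of the same 30. The strongest of these peaks in the IL4 list were near Cish, a suppressor of cytokine signalling, Arg1, the arginase of alternatively activated macrophages, Bcl6, a transcriptional repressor, and Cdh1, the gene of E-cadherin. Near Cish, 9 of 9 IL4 peaks were kept with IFNg+IL4. Near Arg1 it was 4 of 5, near Bcl6 9 of 12 and near Cdh1 3 of 3. Other members had many STAT6 sites, with 15 of 18 peaks kept near Pdcd1lg2, which encodes the checkpoint ligand PD-L2, and 12 of 16 near Mrc1, the mannose receptor. It was 13 of 17 near Il4ra, a chain of the IL4 receptor, and 13 of 14 near Batf3, a transcription factor of dendritic cells. Near Alox15, a lipoxygenase induced by IL4, 2 of 6 peaks were kept, and near Chil3, which encodes a chitinase-like protein, the single weak peak was not.

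Further members of the IL4 response list with STAT6 peaks in both lists were Pparg, a lipid-sensing nuclear receptor (9 of 9 kept), Socs1, an inhibitor of JAK kinases (9 of 9), and Flt1, a receptor for vascular growth factor (9 of 11). Kdm6b, a histone demethylase (4 of 6), was another, as were the lectin genes Mgl2 (5 of 7) and Clec10a (5 of 7). Retnla, which encodes a resistin-like secreted protein, had 3 of 4 peaks kept. For Tgm2, a transglutaminase, and Ccl24, a chemokine, it was 5 of 5 each. For Ch25h, cholesterol 25-hydroxylase, it was 3 of 3, and for Irf4 and Myc, both transcription factors, 3 of 3 and 4 of 4. The 2 list genes with no STAT6 peak in either list were Cd209a and Ccl22, named here after their values were seen. Over the IL4 response list as a whole 152 of 181 IL4 peaks were kept, 84.0% (77.8 to 89.0%), against a median of 75.1% in matched sets of peaks (percentile 99.965). The share kept was also high near IFNg response genes, 97 of 117 peaks or 82.9% (percentile 99.93), and near inflammatory and AP-1 genes, 91 of 110 or 82.7% (percentile 99.96, but 97.0 at a −log10 q of at least 5). Among random genes the IL4 response, IFNg response and inflammatory and AP-1 lists lay at percentiles 99.72, 99.42 and 98.12. Among the control lists, 18 of 19 peaks near genes of other organs were kept (percentile 99.315), a list meant as a negative control. This percentile was 65.5 with a window of 5 kb, 96.9 with 50 kb and 99.98 at a −log10 q of at least 5. Markers of other cell types, the other control list, went the other way. Their difference from peaks of like strength was −12.7 points (percentile 4.91 among random genes). Peaks near macrophage identity genes (117 of 170, 68.8%) and growth genes (31 of 45, 68.9%) lay at percentiles 10.1 and 91.8. Among random genes these were 18.6 and 88.1.

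Among STAT6 peaks found with IFNg+IL4, those near IFNg response genes were less often present with IL4 alone than other peaks of like strength. Of 145 such peaks 95 were also in the IL4 list, 65.5% (57.2 to 73.2%), against 80% in matched sets (percentile 0). In 2 genes of the list a STAT6 peak was found only in the IFNg+IL4 list: Il12b, which encodes the p40 chain of interleukin 12, and Ifit1, an interferon-induced antiviral gene, both named after their values were seen. Peaks near macrophage identity genes lay on the other side, with 120 of 126 (95.2%) also in the IL4 list (percentile 100). The strongest STAT6 peaks absent from the IL4 list were inside Panx1, a channel gene (chromosome 9, 15015201 to 15015904), and inside the kinase gene Camk1d (chromosome 2, 5625945 to 5626488). Another lay 18.9 kb from Il10ra, a chain of the interleukin 10 receptor (chromosome 9, 45287410 to 45288348). The strongest absent from the IFNg+IL4 list were inside Armc9 (chromosome 1, 86186348 to 86186844) and 43.5 kb from Auh (chromosome 13, 52791473 to 52791879). The strongest shared peaks were inside Gm33049 (chromosome 15, 88855172 to 88856047) and 5.24 kb from Cish (chromosome 9, 107307198 to 107308456).

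Over all STAT6 peaks, 17135 of 24927 IL4 peaks were kept with IFNg+IL4, 68.7% (68.2 to 69.3%), against 0.530% when the second list was shifted along the chromosomes. The share ran from 32.5% in the weakest 10% of the IL4 peaks to 100% in the strongest. In the other direction 17245 of 21481 peaks, 80.3% (79.7 to 80.8%), were in the IL4 list, and both libraries had a similar depth (1.13 and 1.08 times the input).

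STAT6 peaks lay near every one of the 25 macrophage identity genes in both lists, near 33 and 35 of the 35 IFNg response genes, 26 and 28 of 30 inflammatory and AP-1 genes, and 24 and 23 of 30 ribosome biogenesis and growth genes, all above the 99.9th percentile. Markers of other cell types that such a culture could hold (8 and 7 of 25) and genes of other organs (7 and 8 of 25) lay at percentiles from 5.11 to 19.8. STAT6 in untreated cells was not analysed here.

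With IFNg IRF1 peaks were listed near most genes of the IFNg response list, among them genes of antigen presentation and antiviral defence. Peaks lay near 5 of 35 IFNg response genes in untreated cells and near 29 of them after 4 h of IFNg. The 5 with an untreated peak were Psmb8 and Psmb9, subunits of the immunoproteasome, and their neighbour Tap1, the peptide transporter of antigen presentation, which share their peaks, Socs1, and Igtp, an immunity-related GTPase. The 24 genes with a peak only with IFNg included B2m, the light chain of MHC class I (3 peaks), and Nlrc5 and Ciita, the activators of MHC class I and class II genes (3 and 2). Stat2 and Irf9, which transmit interferon signals, had 1 and 2, and Irf1 itself had 1. They also included the guanylate-binding protein genes Gbp2, Gbp3 and Gbp5 (2, 4 and 2 peaks) and the antiviral genes Ifit1, Rsad2 and Isg15 (1, 2 and 1). Others were Cd274, which encodes the checkpoint ligand PD-L1 (2), and the chemokine genes Cxcl10 and Ccl5 (2 each). Irf7, Irf8, Nos2, Cxcl9, Icam1 and Il12b, named after their values were seen, had none in either list.

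With IFNg+IL4 IRF1 peaks lay near 32 of the 35 genes, including each of the 29 with a peak with IFNg alone. Of all protein-coding genes 18.0% had an IRF1 peak with IFNg and 29.7% with IFNg+IL4, from a library 2.08 times as deep. The added peaks named here therefore cannot be told apart from the longer list. Near Socs1 5 of 5 IFNg peaks were kept and 3 more were listed, near Cd274 2 of 2 and 3 more, and near B2m 3 of 3 and 2 more. It was 2 of 2 and 3 more near Rsad2 and 1 of 1 and 4 more near Irf1. Near Irf9 2 of 2 peaks were kept, near Gbp3 4 of 4, near Nlrc5 3 of 3, near Irgm1, a GTPase of autophagy in infected cells, 2 of 2, and near Gbp2 1 of 2. The 3 genes with an IRF1 peak only with IFNg+IL4 were Irf7 (3 peaks), Irf8 and Nos2, the inducible nitric oxide synthase; Irf8 and Nos2 are named after their values were seen. Of 53 peaks near IFNg response genes 52 were kept, 98.1%, the same as the median of matched sets.

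The strongest IRF1 peaks found with IFNg and not untreated lay 94.1 kb from Ralgapa2 (chromosome 2, 146606129 to 146606784), inside Msi2, an RNA-binding protein gene (chromosome 11, 88693099 to 88693465), and 3.78 kb from Trim30c (chromosome 7, 104404429 to 104405080). All 3 were kept with IFNg+IL4. Untreated cells shared strong peaks with IFNg at the end of Rnf44 (chromosome 13, 54693737 to 54694557) and of Flcn, the folliculin gene (chromosome 11, 59809746 to 59810379). Every IFNg peak in the strongest 30% was kept with IFNg+IL4. The strongest that were not kept ranked 1312 and 1377 of 4189 and lay 9.16 kb from Adgb (chromosome 10, 10484156 to 10484337) and 19.7 kb from Ubl3 (chromosome 5, 148484933 to 148485060), and the next were 43.7 kb from Il12b and 3.31 kb from Fas, a death receptor gene. The strongest found only with IFNg+IL4 was 10.6 kb from Cnot4 (chromosome 6, 35144030 to 35144816).

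Of 244 untreated IRF1 peaks 231 were kept with IFNg, 94.7% (91.1 to 97.1%), and the IFNg list was 17.2 times as long although its library was 0.290 times as deep. This share was 86.1% with a reciprocal overlap of 50% and 27.0% against the same number of strongest IFNg peaks. Higher enrichment of the whole IFNg library was not tested for the untreated and IFNg lists, so the longer list cannot be told apart from it. Of 4189 IFNg peaks 3986 were kept with IFNg+IL4, 95.2% (94.5 to 95.8%), and those with no untreated peak in 94.9% of 3957 cases. In the other direction 3916 of 8226 IFNg+IL4 peaks were in the IFNg list, 47.6% (46.5 to 48.7%). The IFNg+IL4 library was 2.08 times as deep as the IFNg library, and with its list thinned to the lower depth, an alternative chosen after the data were seen, the ratio of peak numbers was 1.49 instead of 1.96.

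IRF1 peaks lay near 13 and 21 of 25 macrophage identity genes with IFNg and IFNg+IL4, near 12 and 17 of 30 IL4 response genes, and 8 and 15 of 30 inflammatory and AP-1 genes. The other lists had 5 and 11 of 30 growth genes, 3 and 5 of 25 markers of other cell types and 5 and 5 of 25 genes of other organs. In these lists 2 calls did not hold under every alternative: inflammatory and AP-1 genes with IFNg (percentile 98.11) fell to 94.6 with a window of 50 kb, and IL4 response genes with IFNg+IL4 (99.885) to 95.4 with a window of 5 kb. Untreated IRF1 peaks lay near 2 of 30 IL4 response, 2 of 30 growth, 3 of 30 inflammatory and AP-1, 2 of 25 macrophage identity, 0 of 25 other cell type and 4 of 25 other organ genes. The 4 of other organs placed at percentile 99.87, the same side as the IFNg response list, and with a window of 5 kb these fell to 82.3 and 93.8.

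JUNB peaks were listed near 15 of 35 IFNg response genes in untreated cells and near 26 with IFNg. The 11 genes with a JUNB peak only with IFNg included Cd274 (5 peaks), Cxcl9, a T-cell-attracting chemokine (3), Ifit2 and Ifit3 (3 and 2, in part the same peaks), Rsad2 (2) and Cd40, a costimulatory receptor (1). At genes listed in both, Cxcl10 had 2 peaks untreated and 6 with IFNg, Ccl5 had 1 and 5, Gbp3 had 2 and 5, Ciita had 1 and 3, and Nos2 had 1 and 2. Of 60 IFNg peaks near IFNg response genes 18 were also in the untreated list, 30.0% (18.8 to 43.2%), against 56.7% in matched sets (percentile 0).

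Near inflammatory and AP-1 genes JUNB was already listed at 24 of 30 genes untreated and 24 with IFNg, 21 of them the same. Near Ccl2, a monocyte chemokine, 4 of 4 untreated peaks were kept with IFNg, near Il1b, which encodes interleukin 1 beta, 2 of 3, and near Tnf, a cytokine of acute inflammation, 2 of 4. It was 3 of 4 near Ccl3, a chemokine, 2 of 4 near Il10, an anti-inflammatory cytokine, 2 of 3 near Atf3, a stress-induced factor, and 2 of 2 near Nfkbiz, an inhibitor kappa B family member. The AP-1 genes Fosl2, Jun and Jund had a peak only untreated, and Il6, Ptgs2, the inducible cyclooxygenase, and Thbs1 only with IFNg. Of these, all but Il6 are named after their values were seen. The untreated list was thresholded on p and could hold weaker peaks, so losses from it cannot be told apart from that threshold. Of 51 IFNg peaks near macrophage identity genes 42 were in the untreated list, 82.4% (69.1 to 91.6%), against 56.9% in matched sets (percentile 100).

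With IFNg+IL4 JUNB peaks lay near 19 of the 26 IFNg response genes that had one with IFNg, and near 16 of 24 inflammatory and AP-1 genes. The 7 IFNg response genes without one included Irf1, Cxcl9, Il12b, Nlrc5, Igtp and Rsad2, all but Rsad2 named after their values were seen. Near Cxcl10 1 of 6 IFNg peaks was kept, near Ccl5 2 of 5, near Gbp3 2 of 5, near Ifit2 1 of 3, near Tnf 1 of 3, and near Nos2 1 of 2. Over the lists, 31 of 60 IFNg peaks near IFNg response genes were kept, 51.7% against 58.3% in matched sets (percentile 13.5), and 26 of 40 near inflammatory and AP-1 genes, 65% against 60% (percentile 76.3). Other genes held most of their JUNB peaks, among them Ccl2 (4 of 4), Cd274 (4 of 5), Gbp2 (3 of 3), Mmp9, a matrix metalloprotease (3 of 3), and Socs3, the inhibitor of interleukin 6 signalling (3 of 4). It was 2 of 2 each near Slamf8, Il10, Il1b, Irf8 and Gbp5. JUNB peaks near IL4 response genes in the IFNg+IL4 list were less often in the IFNg list than peaks of like strength, 22 of 35 or 62.9% (44.9 to 78.5%) against 82.9% (percentile 0.17). Of that list Arg1, Cish, Batf3 and the arginine transporter gene Slc7a2 had a JUNB peak with IFNg+IL4 and none with IFNg. These 4 are named after their values were seen. Another 4 genes of the list had a JUNB peak with IFNg and none with IFNg+IL4, and 12 had one in both.

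The strongest JUNB peaks found with IFNg and not untreated were inside Etv6, a repressor gene (chromosome 6, 134225447 to 134226087), and 2.74 kb from Ppt1, a lysosomal thioesterase gene (chromosome 4, 122833025 to 122833853), and both were kept with IFNg+IL4. Peaks not kept lay 25.2 kb from Slc25a54 (chromosome 3, 109055035 to 109055526) and inside Apaf1, a gene of the apoptosome (chromosome 10, 91076754 to 91077103). A peak 10.8 kb from Prdm1, a repressor of lymphoid and myeloid cells (chromosome 10, 44539156 to 44539639), was listed only with IFNg+IL4. The strongest shared peaks of the IFNg list were 27.0 kb from Otud1 (chromosome 2, 19630341 to 19631079) and, among others, 56.7 kb from Nfkbiz (chromosome 16, 55754327 to 55755108).

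Of 9229 untreated JUNB peaks 4332 were kept with IFNg, 46.9% (45.9 to 48.0%), and the share was 63.6% at a −log10 q of at least 2 in both lists and 77.5% at 5. Of 7428 IFNg peaks 4602 were kept with IFNg+IL4, 62.0% (60.8 to 63.1%), from 26.6% in the weakest 10% to 99.7% in the strongest. IFNg peaks with no untreated peak were kept in 1472 of 3069 cases, 48.0% (46.2 to 49.7%), against 71.8% of those with one and 56.4% in matched sets (percentile 0). The untreated JUNB list was thresholded on p and the other lists on q: 3874 of its 9229 peaks had a −log10 q below 2. The ratio of IFNg to untreated peak numbers was therefore 0.805 as deposited, 1.39 at a −log10 q of at least 2 in both lists, which was chosen after the data were seen, and 2.26 at 5, so the direction of this ratio depended on the threshold. At a −log10 q of at least 5 the untreated calls of the IFNg response and IL4 response lists fell to percentiles 95.6 and 85.2. JUNB peaks lay near 17, 16 and 16 of 30 IL4 response genes (untreated, IFNg, IFNg+IL4) and 23, 20 and 17 of 25 macrophage identity genes. They lay near 7, 4 and 3 of 30 growth genes, 7, 7 and 5 of 25 markers of other cell types and 4, 4 and 4 of 25 genes of other organs.

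CEBPB had 5540 peaks untreated, 21499 with IFNg and 6278 with IFNg+IL4. CEBPB peaks lay near 13, 34 and 20 of the 35 IFNg response genes in these 3 lists. They lay near 19, 27 and 21 of 30 inflammatory and AP-1 genes. Of all protein-coding genes 20.7%, 48.2% and 22.4% had such a peak, so gene counts rise and fall with list length. Both gene lists lay at percentile 99.7 or above of random lists each time. Cxcl10 had 1 peak untreated and 9 with IFNg, of which 4 were kept with IFNg+IL4. Nlrc5 had 1 and 8 with 1 kept, Rsad2 1 and 7 with 2 kept, Gbp5 2 and 7 with 3 kept, and Fcgr1, a high-affinity antibody receptor, 1 and 6 with 2 kept. Among inflammatory genes Socs3 had 2 peaks untreated and 10 with IFNg, of which 1 was kept, and Tnf 1 and 7 with 1 kept. The neighbours Ccl3 and Ccl4, which share peaks, had 3 untreated and 7 and 8 with IFNg, with 2 kept. Plaur, the urokinase receptor, had 1 and 5 with 1 kept, and Cxcl1, a neutrophil chemokine, 3 and 4 with 1 kept. Other genes held most of their peaks, with 3 of 3 IFNg peaks kept near Nfkbia, an inhibitor of NF-kappa B, and near Il1b. It was 3 of 4 near Fos, 2 of 3 near Junb and Hmox1, heme oxygenase 1, and 1 of 1 near Ptgs2.

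A CEBPB peak was listed with IFNg and none with IFNg+IL4 near 14 IFNg response genes, among them Irf1, Irf8, Irf9, Ciita, B2m, Irgm1, Isg15 and Ccl5, named after their values were seen. Genes that still had one included Gbp3 (2 of 4 kept), Cxcl9 (2 of 5), Cd40 (2 of 2), Nos2 (1 of 2), Slamf8 (1 of 3) and Ifit2 (1 of 2). Of 105 IFNg peaks near IFNg response genes 14 were in the untreated list, 13.3% (7.49 to 21.4%), against 22.9% in matched sets (percentile 0.01). With IFNg+IL4 26 were kept, 24.8%, against 25.7% in matched sets. Peaks near IL4 response genes were kept more often, 45 of 93 or 48.4% (37.9 to 59.0%) against 28.0% in matched sets (percentile 100). In the other direction 45 of 51 IFNg+IL4 peaks near IL4 response genes were in the IFNg list, 88.2% (76.1 to 95.6%), against 98.0% in matched sets (percentile 0.085, and 2.96 with a window of 5 kb). Near inflammatory and AP-1 genes 37 of 91 were kept, 40.7%, the same as in matched sets.

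The strongest CEBPB peak found with IFNg and not untreated was 0.142 kb from Serpina3f, a serine protease inhibitor gene (chromosome 12, 104214123 to 104214677), and the next lay 23.8 kb from Pdp1, a phosphatase gene (chromosome 4, 11989919 to 11990698). Strong IFNg peaks not kept with IFNg+IL4 lay inside Lrrc8c, a subunit of volume-regulated anion channels (chromosome 5, 105557919 to 105559032), 1.54 kb from Klf3, a repressor gene (chromosome 5, 64834195 to 64834884), and 2.64 kb from Fth1, the ferritin heavy chain (chromosome 19, 9977741 to 9978198). The strongest kept peaks were inside H2aj, a histone gene (chromosome 6, 136808901 to 136809862), inside Ssh2 (chromosome 11, 77386221 to 77386899) and beside Prmt3, an arginine methyltransferase gene (chromosome 7, 49778009 to 49778536). The next were beside Cotl1, which encodes an actin-binding protein, and 69.7 kb from Cebpb itself.

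Of 5540 untreated CEBPB peaks 5532 were kept with IFNg, 99.9% (99.7 to 99.9%), or 78.2% with a reciprocal overlap of 50% and 78.8% against the same number of strongest peaks. Of 21499 IFNg peaks 6069 were kept with IFNg+IL4, 28.2% (27.6 to 28.8%), from 1.58% in the weakest 10% to 99.3% in the strongest. IFNg peaks with no untreated peak were kept in 1859 of 15992 cases, 11.6% (11.1 to 12.1%), and those with an untreated peak in 76.4%. For peaks without an untreated peak, matched sets gave 12.8% (percentile 0). These sets were drawn from all 21499 peaks, 15992 of them without an untreated peak, so they lie near 11.6% by construction. They do not show how much of the difference peak strength accounts for. The 3 libraries had similar depths, 1.46, 1.33 and 1.31 times the input. Compared at the same number of strongest peaks the kept share was 77.7%, and with a reciprocal overlap of 50% it was 18.0%. CEBPB peaks lay near 14, 24 and 20 of 30 IL4 response genes (untreated, IFNg, IFNg+IL4) and 21, 24 and 23 of 25 macrophage identity genes. They lay near 5, 16 and 5 of 30 growth genes, 4, 12 and 5 of 25 markers of other cell types and 3, 8 and 3 of 25 genes of other organs. The counts of these last 3 gene lists lay at percentiles from 15.9 to 84.2 of random lists. The untreated IFNg response call (percentile 99.705) fell to 96.2 with a window of 5 kb.

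**Figure D2:**
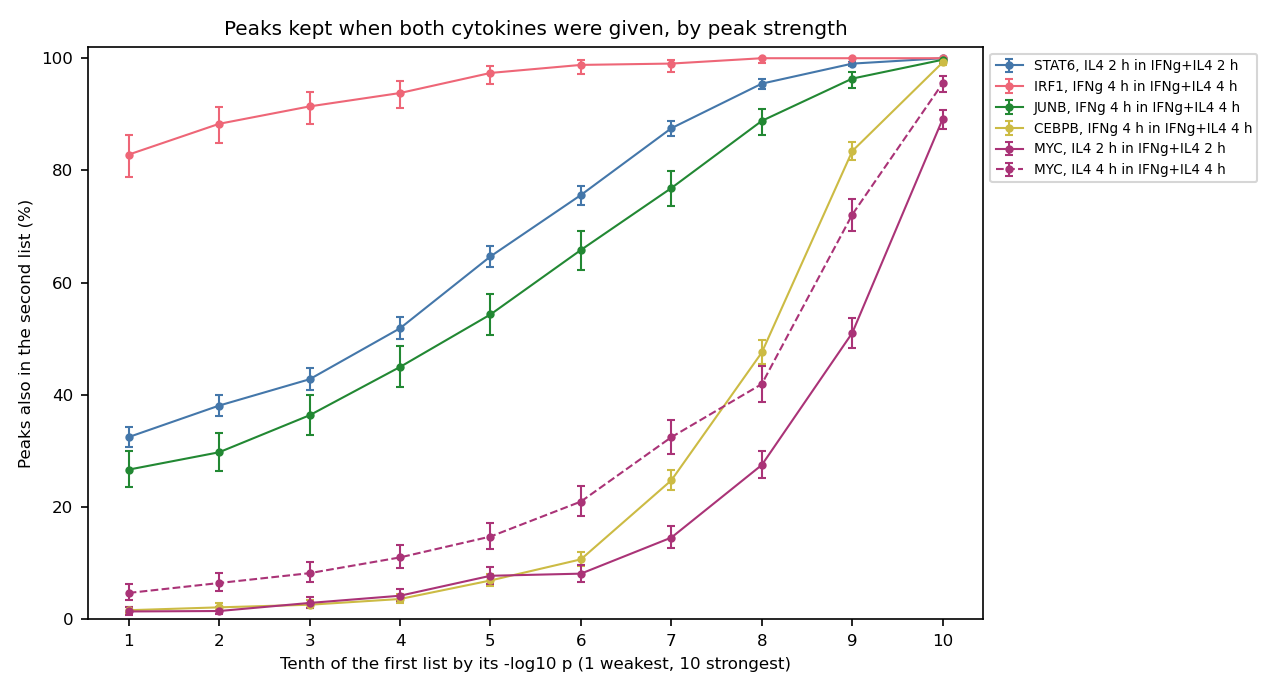
Share of peaks also found with IFNg+IL4 (%, vertical) by class of peak strength in the first list (horizontal, 10 equal classes by −log10 p, 1 weakest, 10 strongest) for STAT6, IRF1, JUNB, CEBPB and MYC at 2 h and 4 h, with exact 95% intervals as error bars. In the weakest 10% 82.8% of IRF1 and 1.58% of CEBPB peaks were kept, and in the strongest 100% and 99.3%.

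MYC peaks lay near a majority of growth genes before treatment and near almost every one of them with IL4. Untreated MYC peaks were near 18 of 30 ribosome biogenesis and growth genes, against a median of 6.67% of genes in random lists (percentile 100), and near 0 of 30 IL4 response genes. After 2 h of IL4 these numbers were 29 and 19. Near Ncl, the nucleolin gene, 1 of 1 untreated peak was kept at 2 h, near Ddx21, a nucleolar helicase, 1 of 1, and near Gnl3, which encodes nucleostemin, 2 of 2. Srm, spermidine synthase, had 2 of 2, Wdr43 and Ppan, ribosome biogenesis factors, 2 of 2 each, and Eif4a1, a translation initiation factor, 3 of 3. Growth genes with a MYC peak only after IL4 included Npm1, nucleophosmin (2 peaks at 2 h), Fbl, the rRNA methyltransferase fibrillarin (2), and Cad, which starts pyrimidine synthesis (2). Odc1, ornithine decarboxylase (2), Cdk4, a cell cycle kinase (1), and Mthfd2, a mitochondrial folate enzyme (2), were others. IL4 response genes with a new MYC peak included Egr2, an IL4-induced factor (5 peaks), Kdm6b (4) and Socs1 (4). The 19 of 30 IL4 response genes lay at percentile 90.7 of random lists, which had a median of 50%, beside 51.1% of all protein-coding genes.

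At 4 h MYC peaks were near 30 growth genes (percentile 100) and 17 IL4 response genes (percentile 89.7). Near growth genes 51 of 59 peaks of the 2 h list were kept at 4 h, 86.4%, against 88.1% in matched sets (percentile 30.5). Among them were 3 of 3 near Wdr43, 4 of 4 near Ppan, 2 of 2 each near Srm, Gnl3, Npm1 and Fbl, 7 of 9 near Eif4a1 and 1 of 2 near Ncl. Near IL4 response genes 36 of 52 were kept, 69.2%, including 4 of 4 near Kdm6b, 3 of 5 near Egr2 and 2 of 4 near Socs1. Near macrophage identity genes 45 of 70 peaks of the 4 h list were in the 2 h list, 64.3% (51.9 to 75.4%), against 91.4% in matched sets (percentile 0). Without Ctsb, Ctsd and Lyz2, left out after their values were seen, it was 43 of 51, 84.3% (71.4 to 93.0%), against 90.2% (percentile 7.04). The strongest 4 h peaks absent at 2 h were inside Grn, progranulin (chromosome 11, 102433963 to 102434331), and Ctsb, cathepsin B (chromosome 14, 63142261 to 63143094 and 63143536 to 63143909), followed by peaks inside Selenop, a selenium transport protein gene, and Tmsb4x, an actin-binding protein gene.

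With IFNg+IL4 MYC peaks at 2 h lay near 27 growth genes and 9 IL4 response genes, and at 4 h near 29 and 7. The IL4 response counts lay at percentiles 87.4 and 53.8 and the growth counts at 100. The 10 IL4 response genes with a MYC peak at 2 h with IL4 and none with IFNg+IL4 were Arg1, Mrc1, Mgl2, Cish, Irf4, Klf4, Pdcd1lg2, Cdh1, Slc7a2 and Flt1, named after their values were seen. Kdm6b had 1 of 4 peaks kept at 2 h, Socs1 1 of 4 and Egr2 1 of 5. At 4 h Kdm6b and Socs1 had 1 of 4 each, Alox15 1 of 1 and Pparg 0 of 1. Near growth genes 38 of 59 peaks were kept at 2 h, 64.4% (50.9 to 76.4%), and 45 of 60 at 4 h, 75.0% (62.1 to 85.3%). These included 3 of 3 near Wdr43 and 2 of 2 near Srm, Gnl3, Npm1 and Fbl at both times and 1 of 2 and 1 of 3 near Ncl. Matched sets gave 62.7% at 2 h (percentile 70.4) and 63.3% at 4 h (percentile 99.91, but 96.6 at a −log10 q of at least 5). Near Nop16, a nucleolar factor, 0 of 2 peaks were kept at 2 h and 1 of 3 at 4 h.

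The kept share near IL4 response genes was 10 of 52 at 2 h, 19.2% (9.63 to 32.5%), against 15.4% in matched sets (percentile 87.0), and 7 of 48 at 4 h, 14.6% (6.07 to 27.8%), against 20.8% (percentile 10.9). IFNg response genes at 2 h kept 19 of 51 peaks, 37.3% (24.1 to 51.9%), against 23.5% (percentile 99.505), and at 4 h 17 of 39, 43.6%, against 33.3% (percentile 92.6). Macrophage identity genes kept 12 of 64 at 2 h, 18.8%, the same as matched sets, and 15 of 70 at 4 h, 21.4% (12.5 to 32.9%), against 35.7% (percentile 0.055), or 15 of 51, 29.4%, against 31.4% (percentile 38.0) without Ctsb, Ctsd and Lyz2. Inflammatory and AP-1 genes kept 6 of 59 at 2 h, 10.2%, against 16.9% (percentile 4.49), and 10 of 37 at 4 h, 27.0%, against 24.3% (percentile 72.3).

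The strongest MYC peaks found with IL4 at 2 h and not untreated were inside Gm33049 (chromosome 15, 88861613 to 88862687), inside Hk2, hexokinase 2 (chromosome 6, 82773124 to 82773989), and beside Xpot, which exports tRNA (chromosome 10, 121625705 to 121627025). Untreated cells shared their strongest peaks 7.79 kb from Myo1g (chromosome 11, 6528416 to 6528971) and inside Ncl (chromosome 1, 86358511 to 86359050). Absent with IFNg+IL4 at 2 h was a peak inside Gnas, a G protein gene (chromosome 2, 174327181 to 174327490). A peak beside Nfkbid, an inhibitor kappa B family member (chromosome 7, 30421300 to 30421433), was listed only with IFNg+IL4, and at 4 h the peaks inside Grn and Ctsb were among those not kept.

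Of 495 untreated MYC peaks 495 were kept with IL4 at 2 h, 100% (99.3 to 100%), in a list 26.7 times as long from a library 1.03 times as deep. With a reciprocal overlap of 50% it was 8.08%, and against the same number of strongest IL4 peaks 67.9%. Higher enrichment of the whole IL4 library was not tested for the untreated and IL4 lists, so the longer list cannot be told apart from it. Of 13211 peaks at 2 h with IL4 8333 were kept at 4 h, 63.1% (62.2 to 63.9%), and 2746 with IFNg+IL4, 20.8% (20.1 to 21.5%), from 1.36% in the weakest 10% to 89.2% in the strongest. Of 9645 peaks at 4 h with IL4 2970 were kept with IFNg+IL4, 30.8% (29.9 to 31.7%). The MYC libraries with IFNg+IL4 had 0.329 and 0.368 times the depth of the input, against 0.573 and 0.876 with IL4 alone. Thinning to the lower depth, an alternative chosen after the data were seen, moved the ratio of peak numbers from 0.230 to 0.301 at 2 h and from 0.353 to 0.556 at 4 h. At the same number of strongest peaks the kept shares with IFNg+IL4 were 65.2% and 65.0%, and with a reciprocal overlap of 50% they were 7.74% and 15.3%. MYC peaks (untreated, IL4 2 h, IL4 4 h, IFNg+IL4 2 h, IFNg+IL4 4 h) lay near 1, 25, 19, 18 and 19 of 35 IFNg response genes and 0, 21, 17, 5 and 9 of 30 inflammatory and AP-1 genes. In the same order they lay near 1, 21, 22, 8 and 7 of 25 macrophage identity genes, 0, 9, 9, 3 and 2 of 25 markers of other cell types and 0, 9, 7, 3 and 2 of 25 genes of other organs.

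**Figure D3:**
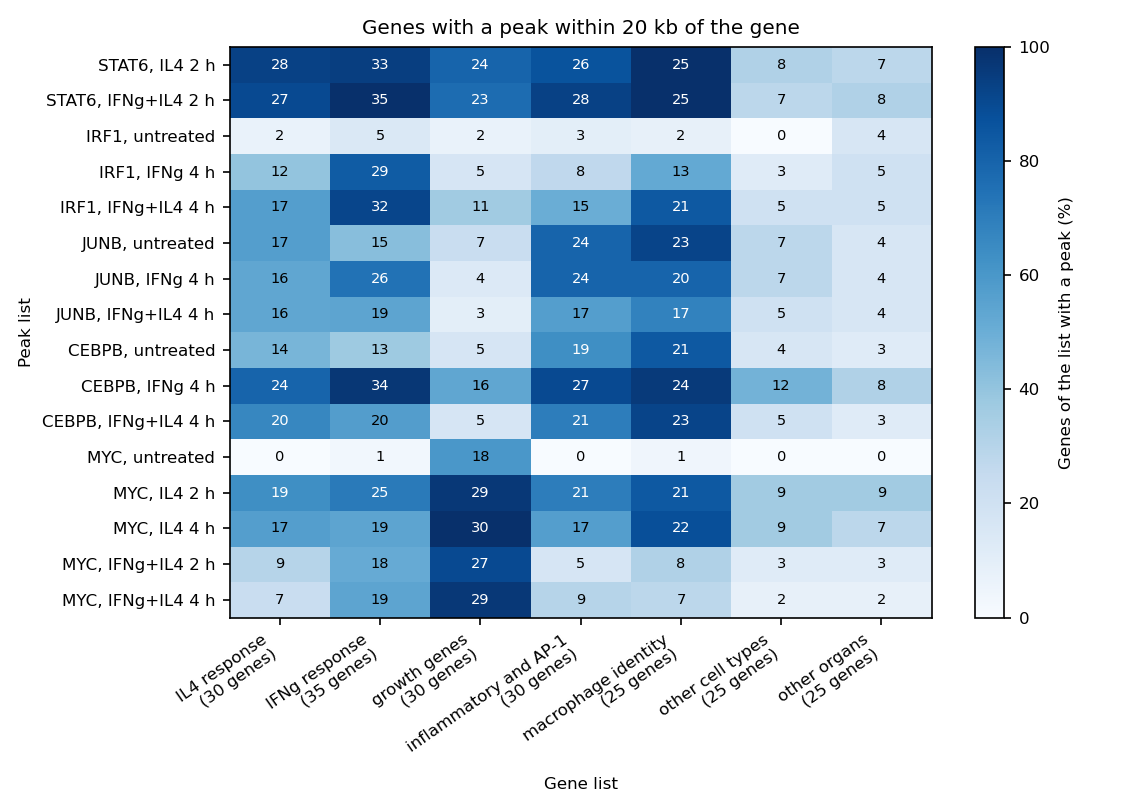
Number of genes with a peak within 20 kb (numbers in cells) and the share of the list (colour, %) for the 16 ChIP peak lists (vertical) and the 7 gene lists (horizontal), without error bars. CEBPB peaks lay near 34 of 35 IFNg response genes with IFNg and near 20 with IFNg+IL4, and MYC peaks lay near 18 of 30 growth genes untreated and near 30 after 4 h of IL4.

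Peaks of different factors were compared within each treatment. JUNB peaks lay under CEBPB peaks in 21.3% of cases untreated, 58.1% (57.0 to 59.2%) with IFNg and 29.3% (28.1 to 30.5%) with IFNg+IL4, and IRF1 peaks under CEBPB peaks in 26.8% with IFNg and 11.3% with IFNg+IL4. JUNB peaks under IRF1 peaks made up 13.3% with IFNg and 28.1% with IFNg+IL4. MYC peaks at 2 h lay under STAT6 peaks in 42.8% of cases with IL4 and 38.4% with IFNg+IL4, and STAT6 peaks under MYC peaks in 22.4% and 5.34%. These shares move with the lengths of both lists, and the shares after shifting lists along the chromosomes were all under 0.6%. With a reciprocal overlap of 50% the 4 shares tested (JUNB under CEBPB with IFNg and IFNg+IL4, IRF1 under CEBPB with IFNg, and MYC under STAT6 with IL4) were all lower, by up to 23.0 points.

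Lost peaks were set beside matched sets drawn from all peaks of their list. Where most peaks were lost, as for CEBPB, these sets lie near the lost share by construction. The STAT6 lists are from 2 h and the IRF1, JUNB and CEBPB lists used here from 4 h. Some comparisons also cross treatments, so the overlaps do not show binding at the same time in the same cells. CEBPB peaks lost with IFNg+IL4 lay under STAT6 peaks of IFNg+IL4 in 22.7% of cases (22.0 to 23.4%) and kept ones in 53.1%. Matched sets gave 27.0% (percentile 0). The share was also below that of matched sets under each of the other lists tested: STAT6 of IL4 (24.3% against 28.6%), IRF1 of IFNg and IFNg+IL4 (4.56% against 4.78% and 8.40% against 9.44%) and JUNB of both (14.5% against 16.3% and 9.92% against 12.5%). JUNB peaks lost with IFNg+IL4 lay under STAT6 peaks in 42.1% and kept ones in 65.3%, with 51.7% in matched sets (percentile 0), and were also low under IRF1 peaks of IFNg+IL4 (18.2% against 21.9%, percentile 0). Under IRF1 peaks of IFNg (10.9% against 11.9%) and CEBPB peaks of IFNg+IL4 (22.2% against 23.4%) they lay at percentiles 1.44 and 1.80, and under CEBPB peaks of IFNg (51.7% against 52.0%) at 31.2. STAT6 peaks lost with IFNg+IL4 lay under IRF1 peaks of IFNg in 1.00% (0.792 to 1.25%) and kept ones in 5.13%, with 3.88% in matched sets (percentile 0). They were likewise low under CEBPB peaks of IFNg (18.7% against 24.0%), JUNB peaks of IFNg (5.92% against 11.6%) and MYC peaks of IL4 at 2 h (17.9% against 23.3%), each at percentile 0. Of STAT6 peaks found only with IFNg+IL4, 616 of 4236, 14.5% (13.5 to 15.6%), lay under IRF1 peaks of IFNg, against 5.18% of the other STAT6 peaks and 6.87% in matched sets (percentile 100).

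Sites near a gene end, within 1 kb of either end of a protein-coding gene, made up 77.0% (71.3 to 82.2%) of untreated IRF1 peaks, 15.1% with IFNg and 15.6% with IFNg+IL4. MYC peaks lay there in 73.9% of cases untreated, 54.4% and 58.9% after 2 h and 4 h of IL4, and 67.4% and 63.9% with IFNg+IL4. STAT6 had 16.1% and 15.5%, CEBPB between 10.6% and 11.4%, and JUNB between 5.49% and 7.45%.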

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

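The tests of depth and enrichment in this part were chosen after the results were seen, as were their bounds, while the count of input peaks was planned.

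The input list is outside the comparisons and still held peaks shared with ChIP lists, which is why it is named here. Of its 128 peaks 43 were overlapped by a peak of at least 1 ChIP list, 33.6% (25.5 to 42.5%). They fell in 7 of the 16 lists, with 24 in IRF1 IFNg, 15 in IRF1 IFNg+IL4, and 5, 24, 8, 35 and 31 in the MYC lists (untreated, IL4 2 h, IL4 4 h, IFNg+IL4 2 h, IFNg+IL4 4 h), and 0 in any STAT6, JUNB or CEBPB list. These 7 were the libraries with less depth than the input. No explanation was tested, and ChIP peaks at these places were left out of the comparisons as reported and kept in 1 of the alternatives.

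MYC had fewer peaks with IFNg+IL4 than with IL4 alone, and the IFNg+IL4 libraries were also shallower. Thinned to equal depth, the ratio of peak numbers was 0.301 (0.299 to 0.303 over the draws) at 2 h and 0.556 (0.549 to 0.563) at 4 h, which argues against depth as the whole cause. Lower enrichment in the whole IFNg+IL4 library could not be told apart from fewer bound sites at 2 h, where peaks near gene ends were kept 1.88 points more often than matched peaks (percentile 100), outside the spread of random sets but below the bound of 5 points. IFNg response genes at 2 h came nearest among the lists, kept 9.84 points more often than expected (percentile 98.7 among random genes, 99.58 among random peaks), short of the bound. At 4 h the gene-end difference was 0.916 points (percentile 99.91) and that of growth genes 11 points (percentile 98.6 among random genes, short of the bound, and 99.715 among random peaks, past it), so enrichment stays open there. Peaks near macrophage identity genes at 4 h were kept less often than matched peaks (−14.6 points, past the bound in both draws). The bound was not passed when any 1 of Ctsb, Ctsd and Lyz2 was left out, so enrichment stays open there too. Without all 3 the difference was −1.63 points. These 3 were picked for their peaks absent at 2 h and none of those left out with them was kept. Their removal therefore had to shrink the difference. At the 45 of the 70 peaks also listed at 2 h it was 1.20 points. None of the other peaks was kept, so this restriction raised the kept share by construction, from 21.4% to 33.3%. Background at highly transcribed genes, untested, may account for the difference at all 70 peaks, as an effect of IFNg may.

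IRF1 had more peaks with IFNg+IL4 than with IFNg alone, from a library 2.08 times as deep. After thinning the ratio was 1.49 (1.48 to 1.51), and 1.39 at the draw nearest to 1 less the error of thinning, which counts against depth as the whole cause under a bound of 1.1 that was changed with the values in view. The IFNg library would need at most 0.27 of the depth of the other for a ratio within 1.1. The depths recovered were 0.446 and 0.929 times the input, from fits in which part of the values of both libraries lay off the steps. Higher enrichment of the whole library fits the gene-end peaks (0.702 points, percentile 80.3). For macrophage identity genes (−15.1 points) it cannot be told apart from a larger gain there, because the draw of genes passed the bound (percentile 0.12) and the draw of peaks did not (percentile 0.445). An effect of IL4 on IRF1 binding, which the design names, stays open and untested.

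CEBPB had more peaks with IFNg than untreated or with IFNg+IL4. Depth does not account for it, since the IFNg library had 0.915 and 1.01 times the depth of the others. Higher enrichment in the IFNg library fits the gene-end peaks, whose shares differed from matched peaks by −1.17 and 1.17 points (percentiles 1.80 and 98.4), within both bounds. By the bounds set, it is counted as excluded as the whole cause near 2 gene lists. Peaks near IFNg response genes were found untreated less often than matched peaks (−11.3 points, percentile 0.02 among random genes). Peaks near IL4 response genes were kept with IFNg+IL4 more often (19.7 points, percentile 100). Both stayed past the bound without any single gene. The smallest differences were −10.2 and 16.2 points in the draw of genes. In the draw of peaks they were −8.91 (without Gbp3) and 15.9 points (without Pdcd1lg2). Leaving out 1 gene is a weak test where neighbours share peaks. Without Psmb8, Psmb9 or Tap1 the draw of peaks was unchanged at −9.52 points, and these genes were not left out together. For the rest of the 21499 peaks enrichment and added binding sites both stay open, and the other 5 lists did not pass the bound in either draw, which leaves an effect of the cytokines there open. The shift near IFNg response genes was not particular to CEBPB. Against peaks of like strength it was −17.7 points for STAT6 (IFNg+IL4 peaks in IL4) and −28.8 for JUNB (IFNg peaks in untreated). For MYC (IFNg+IL4 peaks in IL4) it was −13.7 at 2 h and −4.19 at 4 h, and for IRF1 (IFNg peaks in untreated) −4.94. Percentiles among random genes were 0, 0, 0.09, 11.4 and 0.49. A cause common to these factors was not tested. CEBPB binding added by IFNg at IFNg response genes and held or gained with IL4 at IL4 response genes is a hypothesis. It was found and tested on the same libraries, and replicate libraries with a CEBPB library of IL4 alone would be needed to decide it.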

How the results depend on the processing

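Alternatives for JUNB at a −log10 q of at least 2, for thinning to equal depth, for peaks gained with IFNg, for overlaps between factors and for leaving out 3 macrophage genes were chosen after the data were seen. The others were planned. As reported, the kept shares were 68.7% for STAT6, 95.2% for IRF1, 62.0% for JUNB and 28.2% for CEBPB (each to IFNg+IL4), and for MYC 63.1% from IL4 2 h to 4 h, 20.8% from IL4 to IFNg+IL4 at 2 h and 30.8% at 4 h. In the same order, with MYC last, a −log10 q of at least 5 in the first list only gave 72.5%, 96.5%, 64.4%, 29.8%, 69.6%, 24.4% and 35.8%. In both lists it gave 67.5% for STAT6, 60.1% for JUNB and 61.9%, 19.3% and 29.0% for MYC. A fold of at least 5 gave 66.8% for STAT6, 94.0% for IRF1, 58.9% for JUNB and 58.6%, 22.3% and 34.4% for MYC. A distance of up to 500 bp gave 71.5% for STAT6, 63.2% for JUNB, 29.3% for CEBPB and 69.7%, 24.5% and 35% for MYC. The summit inside the other peak gave 66.9% for STAT6, 93.9% for IRF1, 60.6% for JUNB and 56.8%, 17.1% and 25.7% for MYC. A reciprocal overlap of 50% gave 61.0%, 67.8%, 58.0%, 18.0%, 51.4%, 7.74% and 15.3%. The kept shares of untreated peaks were 94.7% for IRF1, 46.9% for JUNB and 99.9% for CEBPB (each to IFNg) and 100% for MYC (to IL4 2 h). In this order a reciprocal overlap of 50% gave 86.1%, 39.0%, 78.2% and 8.08%, and the same number of strongest peaks 27.0%, 54.1%, 78.8% and 67.9%. For JUNB it was 63.6% at a −log10 q of at least 2 in both lists, 77.5% at 5 in both, 79.4% at 5 in the first only and 71.5% at a fold of at least 5. For the other 7 pairs the same number of strongest peaks in both lists gave 74.4%, 80.4%, 72.8%, 77.7%, 75.0%, 65.2% and 65.0%. That setting removes the difference in list length by its construction, and for the other settings the cause was not tested. Thinning gave 89.4% for IRF1 and 58.2%, 26.3% and 42.1% for MYC. The ratio of JUNB peak numbers, IFNg over untreated, was 0.805 as deposited and reversed to 2.26 at a −log10 q of at least 5, 2.16 at a fold of at least 5 and 1.39 at a −log10 q of at least 2. The untreated list, thresholded on p, holds 3874 peaks below a −log10 q of 2 that no other list could hold. No other of the 11 ratios changed direction, and at a −log10 q or a fold of at least 5 the other 10 stayed within 1.5 times. Keeping peaks that overlap the input moved none of the 11 shares or 11 ratios beyond its bound. Of 112 shares of list genes near peaks, 106 stayed within the exact 95% interval of the reported share at a −log10 q of at least 5. With a window of 5 kb 86 did (96 shares were lower) and with 50 kb 87 did (92 were higher). These intervals are wide, because the lists are short. Of these 112, 56 lay in the highest 2.5% of random lists as reported, and 52, 51 and 54 of them still did under these settings. Of 132 shares kept near gene lists, 15 lay in the highest 2.5% of random sets and 10 in the lowest. Still there were 9, 11 and 13 of the 15 and 8, 8 and 9 of the 10, and 1 share, of JUNB IFNg peaks near inflammatory and AP-1 genes in the untreated list, moved to the other side of the 50th at a −log10 q of at least 5. The shares of gained peaks kept stayed within their intervals under every setting, the 4 shares of overlap between factors were lower under each setting, and the 16 shares near gene ends were higher at 2.5 kb by up to 9.15 points. Leaving out Ctsb, Ctsd and Lyz2 moved the kept share of MYC IL4 4 h peaks near macrophage identity genes from 64.3% to 84.3% (to IL4 2 h) and from 21.4% to 29.4% (to IFNg+IL4 4 h). Motif alternatives were not run because no genome sequence was used here. Leaving out a replicate was not possible with 1 library per group. No paired analysis was possible because each group was 1 library without a replicate number. Library depths within a pair differed by up to 3.45 times (IRF1 untreated over IFNg, where the deeper library had the shorter list).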

Other observations

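The comparisons of IRF1 untreated peaks with other factors and the genes of the MYC 4 h peaks in this part were chosen after the values were seen.

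Untreated IRF1 peaks formed a small set, mostly at gene ends. Of 632 IRF1 peaks near gene ends with IFNg, 184 were also listed untreated, 29.1% (25.6 to 32.8%), against 1.35% of other IFNg peaks and 8.86% in matched sets (percentile 100). Of the 244 untreated peaks 4, 1.64% (0.448 to 4.14%), lay under the 495 untreated MYC peaks, and 131, 53.7% (47.2 to 60.1%), under the 13211 MYC peaks of IL4 at 2 h. Of the 3957 IFNg peaks without an untreated peak these were 8 and 314, the latter 7.94% (7.11 to 8.82%). Under STAT6 peaks of IL4 it was 43.4% (37.1 to 49.9%) and 21.4%, while under untreated CEBPB peaks it was 2.87% and 3.11% and under untreated JUNB peaks 9.02% and 8.67%. The strongest untreated peaks lay at Rnf44, Mia2, Taf15, Mical3 and Flcn. Those inside Mia2 and Mical3 were 35.8 and 63.5 kb from the nearer gene end. None of these genes is in the IFNg response list, although 5 genes of that list had an untreated peak within 20 kb (percentile 99.875). Of those, Psmb8, Psmb9 and Tap1 share their peaks. Genes of other organs, a negative control, lay at percentile 99.87, and both percentiles fell with a window of 5 kb.

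MYC peaks at macrophage genes differed between the IL4 times by gene, in a 4 h library 1.53 times as deep as that of 2 h. Of the 25 macrophage identity genes 7 had more peaks at 4 h, 9 as many and 9 fewer, with 64 peaks near them at 2 h and 70 at 4 h. Ctsb had 2 peaks at 2 h and 9 at 4 h, Ctsd, another lysosomal protease gene, 2 and 7, and Lyz2, the lysozyme gene, 0 and 3. In the other direction Cd68, a lysosomal membrane protein gene, had 8 and 5, Mertk, a receptor for dying cells, 5 and 3, and Nr1h3, a sterol-sensing nuclear receptor, 4 and 2, and Spi1, the myeloid master factor PU.1, had 6 and 6.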
